A study of Mus musculus with 6 samples.

How the data were processed

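Total RNA from the ascending and the descending aorta of wild-type C57BL/6 mouse embryos, 13.5 days postcoitum, was extracted with Trizol and hybridised as biotinylated cRNA to Affymetrix mouse gene arrays, per the labels' protocols. The groups were taken from the sample labels, which give 3 biological replicates for each segment. The values used are log2 expression of probe sets, deposited by the authors after RMA, which subtracts background, equalises the distributions of the arrays and summarises the probes of a probe set. RMA and Partek 6.6 are named per the submitters' processing notes without settings, and the genome build and annotation behind the probe sets are not given in the sources used here. The log2 scale was read from the values, which ran continuously from 2.53 to 14.6 with medians between 7.14 and 7.22. Because the distributions were made alike before deposit, a change shared by most genes cannot be seen in these values, and RMA pulls small signals toward the background, which makes differences of dim genes smaller. All 6 value columns of the table were used.

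Probe sets were named from the array platform's gene annotation, which is several years old, and the names were set against the symbols of a RefSeq gene table of GRCm38.p6 through the Entrez gene number. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none. The Entrez number matched for 21698 of those with 1 symbol, and 0 symbols needed a change. Only probe sets with 1 symbol were used, and for the 999 genes with more than 1 probe set the 1 with the highest mean over all arrays was kept, which left 19938 genes. No filter on dim genes was applied. Probe sets of related genes such as the Hox and histone genes can share sequence, so small differences between close paralogs are uncertain. Some members of the fixed lists were not analysed here.

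The segments were compared with linear models per gene (lmFit and eBayes of limma 3.58.1 in R 4.3.3) on all 6 arrays without covariates, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All differences are ascending minus descending. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was used for single genes. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 34 lists, and again with the correlation estimated from the data and with fry. With an estimated correlation camera also uses only the degrees of freedom left by the arrays, which are few here, so small p-values are hard to reach. The lists cover axial patterning, embryonic origins of the vessel wall, its matrix, contractile apparatus and signalling, and markers of other cell types that a dissected aorta can hold. A list needed at least 3 measured members. Sex-linked genes were given per array only. Similarity of the arrays was described by Pearson correlation across genes and by principal components of the gene-centred values. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

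The groups, the main test, the lists, the rule for named genes and the alternatives were fixed before the data were examined. By that rule the text names up to 10 genes in each direction with the largest difference among those that passed and whose groups did not overlap, or the 10 with the smallest p when none passed, and of each described list up to 4 members with the smallest unadjusted p. Unnamed transcripts, pseudogenes and small RNA genes were left out. Leaving out each array in turn was among the fixed alternatives. Describing the fit without ascending replicate 3 at length, applying the rule for named genes to it, leaving out descending replicate 1 together with it, and naming further list members that passed only there were decided after the values were seen. No array was moved to the other group.

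The alternatives for the gene test were a repeated quantile normalization, median-centring of the arrays, filters at the 25th and 50th percentile of mean expression, the mean of all probe sets of a gene, all 35556 probe sets, a variance trend with robust estimation, a per-gene test without moderated variance, array weights, the replicate number as a block and a minimum of 2-fold. The scripts were tested on simulated data made from the spread of the real arrays, with 200 of 19938 genes changed in each of 5 data sets. For all 6 arrays, 86.6% of changes of 1 on the log2 scale and 97% of changes of 2 were recovered, and 3.23% of the calls were false. For the 5 arrays without ascending replicate 3, 80.2% and 97.6% were recovered and 3.78% of the calls were false. A list shifted by 0.5 was found by camera at the preset correlation in 5 of 5 data sets in each design. Other lists called per data set were 0 for all 6 arrays and 0.4 without ascending replicate 3. Genes were simulated independently of each other, so the list figures do not hold for lists whose genes are correlated. These figures hold for arrays of a group that differ only by the simulated spread, and not for a fit in which an array was left out because of its values.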

Results

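Gene expression was measured in the ascending and the descending aorta of wild-type C57BL/6 mouse embryos at 13.5 days postcoitum, with 3 arrays for each segment and 6 arrays in all. The values are log2 expression as the authors' RMA processing gave them, and 19938 genes were compared, each through 1 probe set. Array medians lay between 7.14 and 7.22, and single values between 2.53 and 14.6. The labels call the arrays of a segment biological replicates but name no embryo, litter or pool behind them, so the p-values measure the spread between these samples. The small number of arrays limits the precision of every value. No genome build was given in the sources used here, so genes are identified by symbol and, for the leading ones, by the probe set number of the array.

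The comparison asked which genes differ between aortic segments whose smooth muscle has different embryonic origins, largely cardiac neural crest in the ascending aorta and mesoderm in the descending aorta. Hox genes of paralog groups 5 to 8, which carry positional identity in the trunk, were lower as a group in ascending aorta: all 10 measured members had a lower mean there, and the median log2 difference was -0.98 (adjusted p = 0.757 with an estimated correlation between genes). Markers of mesothelium and epicardium, the cell layers that cover body cavities and heart, were higher as a group, with a median difference of 1.05 over 8 genes (adjusted p = 0.757 with an estimated correlation). Cardiac muscle genes were also higher as a group, while endothelial markers and collagens were lower (adjusted p = 0.757 with an estimated correlation for each). These 5 calls rest on limma's camera test at a preset correlation, and none of them was made by fry (adjusted p = 0.497). No single gene passed the test over all 6 arrays, and the array labelled ascending aorta replicate 3 lay with the descending arrays. Without that array 933 genes passed, but the array was singled out by its values, so p-values of that fit are likely too small. Among the largest rises were Hpcal4, Angptl7 and the transcription factors of heart development Tbx20 and Gata5. Among the largest falls were Foxd1 and Hoxc6.

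Over all 6 arrays, 0 of 19938 genes passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.53. At an unadjusted p under 0.05 there were 1852 genes, 790 higher and 1062 lower in ascending aorta, against 997 that chance would give. The per-gene test without moderated variance and the other limma settings also called 0 genes. The 3 ascending arrays lay entirely above or below the 3 descending arrays for 2955 genes, or 14.8%, where chance gives 10%. The 10 named genes with the smallest p are given as values only. Itga7, the laminin-binding integrin alpha 7 subunit of muscle, averaged 7.91 ± 0.40 (SD, n = 3) in ascending and 8.91 ± 0.16 (SD, n = 3) in descending aorta, a difference of -0.997 ± 0.20 (SE). Slc35d3 differed by -0.74, Atp8b1 by -0.64, Olfml2a by -0.48, Mrgprh by -0.48, Ccn5 by -0.47, Rergl by -0.47 and Pcolce2, an enhancer of procollagen processing, by -0.47. Med30, a subunit of the Mediator complex, differed by 0.66 and the histone gene H2ac8 by 0.39.

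**Figure D1:**
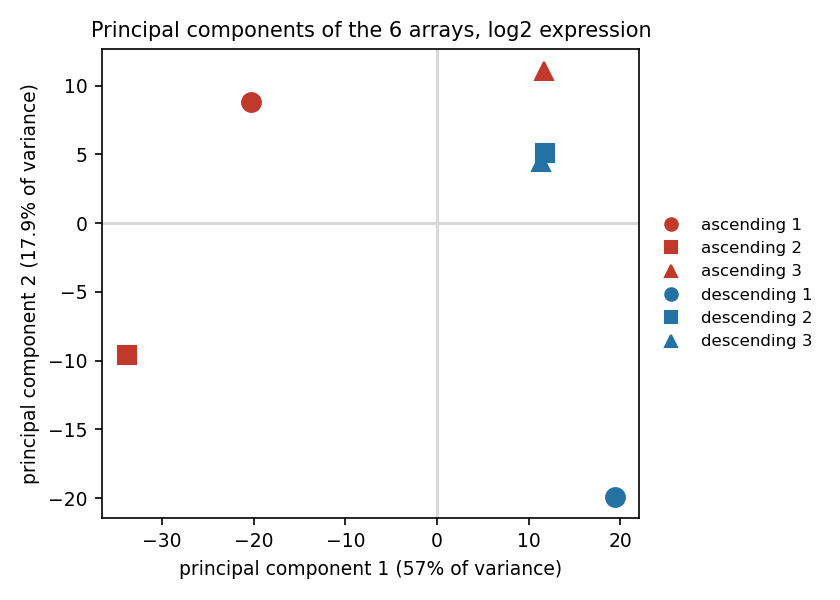
Principal components of log2 expression over all tested genes, with component 1 (57% of the variance) on the horizontal axis and component 2 (17.9%) on the vertical axis, 1 point per array, red for ascending and blue for descending aorta. Ascending replicates 1 and 2 lie at -20.3 and -33.8 on component 1, and ascending replicate 3 lies at 11.6 beside descending replicates 2 and 3 at 11.7 and 11.4.

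Across genes, ascending replicate 3 correlated most closely with descending replicate 3 (Pearson's r = 0.9975). Its mean correlation was 0.996 with the descending arrays and 0.988 with the other ascending arrays, and genes are not independent replicates in these coefficients. Descending replicate 1 stood apart in a different way, at -19.9 on component 2. It gave a level of 5.80 for Xist, the RNA of the inactive X chromosome, where the other arrays gave 10.1 to 11.2. It also gave the highest levels of the Y-linked genes Kdm5d (8.73), Eif2s3y (9.79) and Uty (8.27), where the other arrays gave 7.19 to 8.16 for Kdm5d, 8.29 to 9.51 for Eif2s3y and 6.82 to 7.51 for Uty. On the same array the ribosomal protein genes lay at a median of -0.24 from their mean over arrays and complex I genes at -0.28. In ascending against descending aorta the median difference was 0.17 over 70 ribosomal protein genes and 0.19 over 38 complex I genes, with 0 genes passing the test. Without descending replicate 1 these medians were 0.071 and 0.11.

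Of the members of paralog groups 5 to 8, Hoxc6 (probe set 10427293) averaged 6.87 ± 1.75 (SD, n = 3) in ascending and 8.85 ± 0.15 (SD, n = 3) in descending aorta, and Hoxc8, Hoxa7 and Hoxb6 differed by -1.85 ± 0.70, -1.14 ± 0.43 and -0.53 ± 0.20 (SE). The group was lower in limma's camera test (adjusted p = 2.93e-05 over 34 lists). With an estimated correlation between genes that call was lost (adjusted p = 0.757 with an estimated correlation). No member passed over all genes or adjusted over the list alone, because the ascending arrays did not lie together: the list median, relative to the descending mean, was -1.52 and -1.64 on ascending replicates 1 and 2 and 0.038 on replicate 3. Paralog groups 1 to 4, expressed further toward the head, did not pass (adjusted p = 0.38 by camera). Their median difference over 11 genes was 0.068 (0.0208 without descending replicate 2 and 0.111 without descending replicate 1), the mean was -0.013, and Hoxb2 differed by 0.36 ± 0.11 and Hoxc4 by -0.78 ± 0.30 (SE). Paralog groups 9 to 13 did not pass either (median difference -0.094 over 16 genes, of which 2 lay above the median of all genes in descending aorta, adjusted p = 0.357 by camera, median -0.0372 without descending replicate 1), with Hoxa9 at -1.07 ± 0.44 and Hoxb9 at -0.38 ± 0.18 (SE). Whether the paralog groups differed from each other was not tested.

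**Figure D2:**
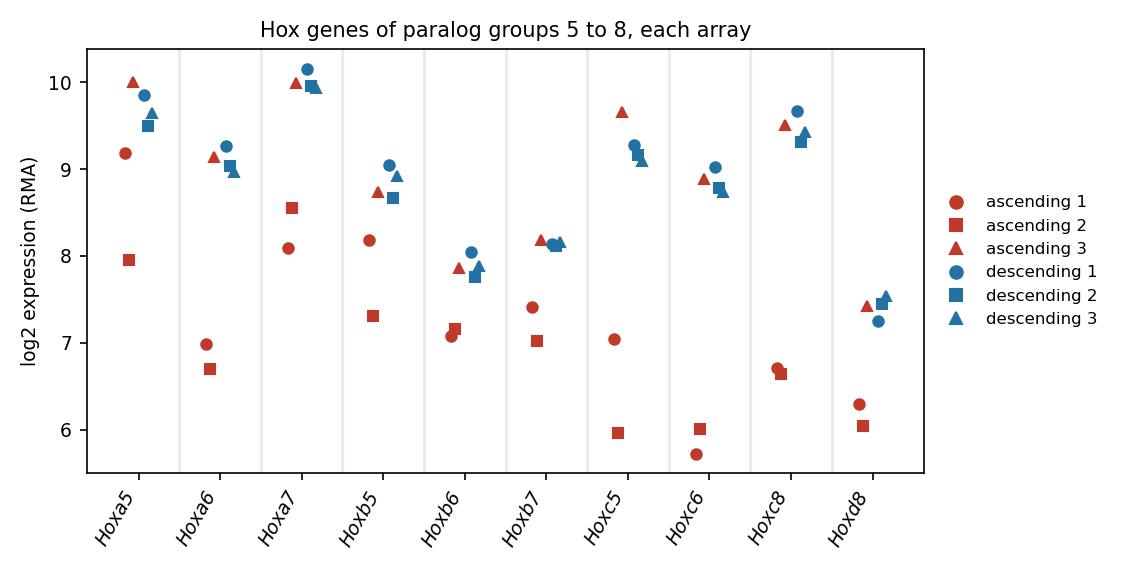
Log2 expression of the 10 measured Hox genes of paralog groups 5 to 8 on the vertical axis, 1 point per array, red for ascending and blue for descending aorta, with circle, square and triangle for replicates 1, 2 and 3. Hoxc6 lies at 5.72 and 6.00 on ascending replicates 1 and 2, at 8.89 on ascending replicate 3, and between 8.74 and 9.02 on the descending arrays.

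Markers of mesothelium and epicardium were higher in ascending aorta in 7 of 8 genes by their means, and the list was higher in the camera test (adjusted p = 2.61e-05 by limma). With an estimated correlation the call was lost (adjusted p = 0.757 with an estimated correlation). Without ascending replicate 3 the median of the list was 1.64. Upk1b and Upk3b, uroplakins made by mesothelium, differed by 1.94 ± 0.56 and 1.64 ± 0.47 (SE), Tcf21, a transcription factor of epicardium and mesenchyme, by 1.41 ± 0.31, and Aldh1a2, which makes retinoic acid, by 0.52 ± 0.20. Adjusted over the list alone, 3 genes were higher, against 0 over all genes. Of the 8 members, 5 also stand in another of the lists, and 5 lay above the median of all genes in descending aorta. Cardiac muscle genes were higher by their means in 16 of 17 members (median 0.20, adjusted p = 0.000124 by camera). That call too was lost under the estimated correlation (adjusted p = 0.757 with an estimated correlation). The cardiac median was 0.0547 without ascending replicate 2 and 0.30 without descending replicate 3. Tnnt2 and Tnni1, troponin subunits of the embryonic heart, differed by 1.47 ± 0.58 and 1.41 ± 0.43 (SE), cardiac actin Actc1 by 0.48 ± 0.10 and the natriuretic peptide gene Nppa by 0.20 ± 0.084. Adjusted over the list alone 1 gene was higher, and 8 of the 17 members lay above the median of all genes in descending aorta. On ascending replicate 3 the median of the mesothelial list was 0.25 and that of the cardiac list -0.18, against 1.70 and 0.22 on replicate 1 and 1.59 and 0.40 on replicate 2. Descending replicates 1, 2 and 3 gave -0.11, -0.029 and 0.11 for the mesothelial list. They gave 0.044, -0.16 and 0.15 for the cardiac list, so descending replicate 3 lay close to ascending replicate 1 there.

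Endothelial markers were lower in ascending aorta in 11 of 12 genes by their means, with a median difference of -0.35 (adjusted p = 3.75e-05 by camera). The call was lost under the estimated correlation (adjusted p = 0.757 with an estimated correlation). Adjusted over the list alone 7 members were lower, among them the junction protein gene Esam at -0.48 ± 0.12, the transcription factor gene Erg at -0.36 ± 0.11, and the VEGF receptor genes Kdr at -0.77 ± 0.25 and Flt1 at -0.50 ± 0.17 (SE). Collagen genes were lower by their means in 14 of 15 members, with a median of -0.33 (adjusted p = 7.45e-05 by camera). Under the estimated correlation this call was lost as well (adjusted p = 0.757 with an estimated correlation). Col14a1 and Col12a1, collagens that associate with fibrils, differed by -1.03 ± 0.35 and -0.92 ± 0.33, Col6a3 by -0.43 ± 0.13 and Col1a1, the main fibrillar collagen chain, by -0.37 ± 0.13 (SE). Adjusted over the list alone 0 collagen genes passed. The endothelial median on ascending replicate 3 was -0.15 and the collagen median -0.044, where replicates 1 and 2 gave -0.45 and -0.48 for endothelium and -0.39 and -0.40 for collagens.

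**Figure D3:**
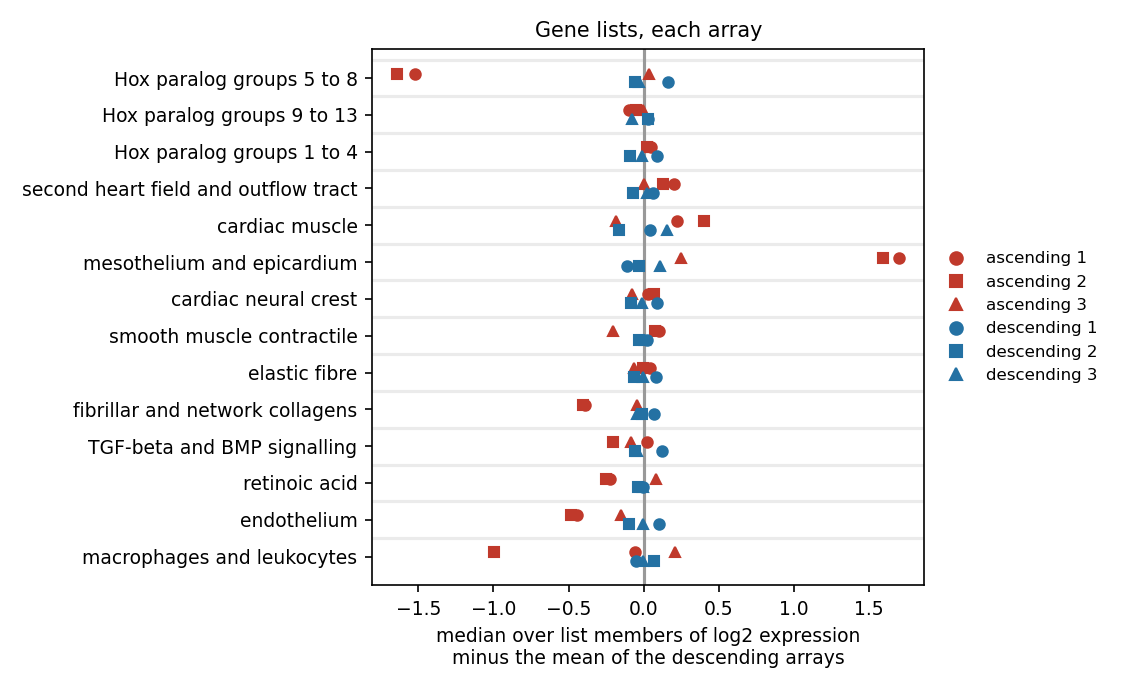
Median over the members of each described gene list of log2 expression minus the mean of the descending arrays, on the horizontal axis, 1 point per array, red for ascending and blue for descending aorta, with circle, square and triangle for replicates 1, 2 and 3. Ascending replicates 1 and 2 lie at 1.70 and 1.59 for mesothelium and epicardium and ascending replicate 3 at 0.25.

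The other described lists did not pass in the comparison of all arrays without a block. Genes of the second heart field and outflow tract, which build the arterial pole of the heart, had a median difference of 0.079 over 17 genes (adjusted p = 0.0636 by camera). The median was 0.0453 without ascending replicate 1 and 0.123 without ascending replicate 2, and among the members were Gata4 at 1.31 ± 0.39, Hand2 at 1.24 ± 0.46, Tbx20 at 1.86 ± 0.74 and Mef2c at -0.40 ± 0.12 (SE). This list passed without ascending replicate 2 and without ascending replicate 3 (adjusted p = 0.0297 and 0.00248 by camera), and both calls were lost under the estimated correlation (adjusted p = 0.732 and adjusted p = 0.345 with an estimated correlation). Cardiac neural crest genes had a median of -0.015 and a mean of 0.11 over 16 genes (adjusted p = 0.626 by camera), and the median was 0.022 after repeated quantile normalization and 0.014 after median-centring. It ranged from -0.0444 without descending replicate 2 to 0.0209 without ascending replicate 2. Smooth muscle contractile genes had a median of -0.0051 and a mean of 0.10 over 20 genes (adjusted p = 0.723 by camera), with a median of 0.024 after median-centring. Without ascending replicate 3 this list was higher, with a median of 0.0885 (adjusted p = 0.0129 by camera, adjusted p = 0.281 with an estimated correlation). Des differed by 1.41 ± 0.49, Myh11, the smooth muscle myosin heavy chain, by -0.53 ± 0.23, Mylk by -0.27 ± 0.096 and Itga8 by -0.28 ± 0.12 (SE). Acta2, the smooth muscle actin, lay between 13.6 and 13.8 on all 6 arrays. Elastic fibre genes had a median of -0.0045 over 12 genes and 0.025 after median-centring (adjusted p = 0.834 by camera), and Mfap5, a microfibril protein gene, differed by -0.65 ± 0.20 (SE). Genes of TGF-beta and BMP signalling had a median of -0.066 over 30 genes (adjusted p = 0.278 by camera), which was -0.0313 without descending replicate 1 and -0.106 without descending replicate 2, with Tgfb3 at -0.65 ± 0.16, Ltbp2 at -0.79 ± 0.20 and Bmper at -0.56 ± 0.17 (SE). Retinoic acid genes had a median of -0.078 over 15 genes (adjusted p = 0.38 by camera), which was -0.0332 without descending replicate 1. Without ascending replicate 3 that list was lower, with a median of -0.25 (adjusted p = 0.00522 by camera, adjusted p = 0.278 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.25 over 12 genes (adjusted p = 0.18 by camera). The macrophage list passed without ascending replicate 1 and without ascending replicate 3 (adjusted p = 0.0491 and 0.000236 by camera), and both calls were lost under the estimated correlation (adjusted p = 0.86 and adjusted p = 0.683 with an estimated correlation). Without ascending replicate 2 the macrophage median was 0.0816. Over all 6 arrays without a block, no list outside the 5 called passed, and the highest adjusted p was 0.953, for skeletal muscle.

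Leaving out each array in turn gave 0 genes in 5 of the fits and 933 genes, 412 higher and 521 lower in ascending aorta, without ascending replicate 3 (limma, 5 arrays). All 933 had the same sign over all 6 arrays, and 582 of them had an unadjusted p under 0.05 there. The fit of 6 arrays holds the same 5 arrays that called these genes, so the shared sign was nearly fixed in advance. Ascending replicate 3 was singled out by its values. Without it the median SD over genes in ascending aorta went from 0.118 to 0.0953. The p-values and SEs of this fit are therefore likely too small. Without ascending replicate 3 a difference of at least 2-fold was reached by 270 genes, 112 higher and 158 lower. Among the genes that were higher, Tbx20 (probe set 10591853) stood at 10.5 and 10.8 on ascending replicates 1 and 2 against 7.78 ± 0.29 (SD, n = 3) in descending aorta, a 7.18-fold difference (adjusted p = 0.000247 by limma). Gata5 rose by 2.77 ± 0.28 (SE) on the log2 scale, and Popdc2, a membrane protein gene of striated muscle, by 2.48 ± 0.13. The desmosomal cadherin genes Dsg2 and Dsc2 rose by 2.63 ± 0.20 and 2.59 ± 0.11 (SE), and Upk1b by 2.70 ± 0.11. Hpcal4 and Angptl7 each rose by 2.91, Gabra2, a GABA receptor subunit, by 2.56 and the interferon-inducible GTPase Iigp1 by 2.39. Ascending replicate 3 gave 7.66 for Tbx20, 7.52 for Gata5 and 6.71 for Dsc2, against descending means of 7.78, 7.71 and 6.56. It lay above all 3 descending arrays for Dsc2, and also for Upk1b (8.002 against a descending mean of 7.57), Gata4 (8.89 against 8.60) and Tcf21 (8.03 against 7.43). Upk1b, Gata4 and Tcf21 were picked for this after their values were seen. Over all genes, ascending replicates 1 and 2 lay beyond all 3 descending arrays on the same side for 6877. Ascending replicate 3 lay on that side too for 2955 of these.

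Among the genes that were lower without ascending replicate 3, the forkhead factor gene Foxd1 (probe set 10406845) stood at 6.92 and 6.10 on ascending replicates 1 and 2 against 9.92 ± 0.11 (SD, n = 3) in descending aorta, a 10.7-fold difference (adjusted p = 0.000261 by limma). Hoxc6 fell by 2.99 ± 0.13 (SE) on the log2 scale, Hoxc8 fell by 2.79 ± 0.12 and Hoxc5 fell by 2.67 ± 0.27. Emcn, an endothelial sialomucin, fell by 2.48 ± 0.15 (SE), and Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, fell by 2.88 ± 0.24. Agtr2, the type 2 angiotensin receptor, fell by 2.38 ± 0.20, and Fmo1, a flavin monooxygenase, by 2.65 ± 0.19 (SE). Arhgap20 fell by 2.73 and Lgi1 fell by 2.49. Ascending replicate 3 gave 10.3 for Foxd1 against a descending mean of 9.92, above all 3 descending arrays and so away from the other ascending arrays. For Emcn it gave 11.8 against a descending mean of 11.9. For Lyve1 it gave 9.90, below all 3 descending arrays at 10.3 to 10.6. Over the 933 genes its median position was 0.0457 on a scale from 0 at the descending mean to 1 at the mean of the other ascending arrays.

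In the same fit 10 lists passed the camera test, 4 higher and 6 lower, and none of them passed with an estimated correlation, where the lowest adjusted p was 0.21. Limma's fry, which asks whether the genes of a list move one way on balance, called 7 lists (lowest adjusted p = 0.00699). Of the Hox genes of paralog groups 5 to 8, 9 of 10 fell and Hoxa5 did not pass, at -1.10 ± 0.31 (SE). In paralog groups 1 to 4 only Hoxc4 passed of 11 genes, falling by 1.16, and in paralog groups 9 to 13 Hoxa9 and Hoxb9 fell by 1.66 and 0.58 while 14 genes did not pass. Of the mesothelial list Upk1b, Upk3b, Tcf21, Krt19 and Msln rose, and 3 members did not pass: Wt1, Tbx18 and Aldh1a2. Cardiac muscle genes divided: Tnnt2, Tnni1 and Myl3 rose by 2.23, 1.97 and 0.94, and 14 members did not pass, among them Actc1 at 0.48 and Nppa at 0.24. Of the second heart field list Tbx20, Hand2, Gata4, Isl1 and Gata6 rose and Tbx1 fell by 0.89. Of the smooth muscle contractile list Des, the intermediate filament desmin, rose by 2.05, Synpo2, an actin-bundling protein gene, by 1.95 and Lmod1 by 0.54, and 17 members did not pass.

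On the lower side of that fit, Emcn, Kdr, Cdh5 and Esam of the 12 endothelial markers fell, Kdr by 1.07 and Cdh5, the VE-cadherin gene, by 0.59. Of 15 collagen genes Col8a1 fell by 2.05, Col14a1 by 1.43, Col12a1 by 1.35, Col1a1 by 0.51 and Col4a2 by 0.48. Of the 12 macrophage and leukocyte markers Mrc1, the mannose receptor, fell by 1.56 and Cd68 by 0.71. Ascending replicates 1 and 2 differed in that list, with medians of -0.062 and -0.996. Of 15 retinoic acid genes Crabp1, a binding protein, fell by 1.82, Stra6, a retinol transporter, by 1.29, Aldh1a3 by 1.26 and Aldh1a1 by 0.60. Of 6 markers of Schwann cells and glia Fabp7 fell by 1.82, and that list was lower (adjusted p = 0.0318 by camera, adjusted p = 0.683 with an estimated correlation), while 5 members did not pass. Of 30 genes of TGF-beta and BMP signalling 6 fell, among them Tgfb3 by 0.83, Ltbp2 by 0.92 and Bmper by 0.75, and the list did not pass (adjusted p = 0.138 by camera). No elastic fibre gene passed, and of 16 cardiac neural crest genes only Hand2 and Sema3c rose, by 1.83 and 0.83. With descending replicate 1 left out as well, 469 genes passed, 233 higher and 236 lower, and 11 lists at the preset correlation, against 0 with an estimated correlation and 5 with fry.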

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

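Leaving out 2 arrays together, the estimated correlation and fry in fits without an array or with the replicate block, and the settings for the similarity of the arrays were chosen after the values were seen, and the other alternatives before. The count of genes stayed at 0 under every alternative that kept all 6 arrays, the per-gene test without moderated variance and the replicate block included. Leaving out 1 array gave 0 to 933 genes (0 to 412 higher, 0 to 521 lower) and 5 to 10 lists, and the high ends came without ascending replicate 3. Without that array and descending replicate 1, the counts were 469 genes (233 higher, 236 lower) and 11 lists. Over all 6 arrays the number of lists was 0 with an estimated correlation and 0 with fry. The adjusted p of the 5 called lists was then 0.757 and 0.497, with the same medians, so those calls stand only at camera's preset setting. Estimating the correlation also lowers the degrees of freedom, so the change cannot be put down to the correlation alone. Hox paralog groups 9 to 13 had an estimated correlation of 0.0111, close to the preset. Their unadjusted p by camera still went from 0.186 to 0.259. Fry is another kind of test and does not check the preset. By camera with an estimated correlation the unadjusted p of the 5 called lists lay between 0.0731 and 0.172. How often that setting finds a shifted list was not simulated, so a lost call does not show that a list is unchanged. Same-numbered arrays of the segments deviated from their group means with correlations of -0.0798, -0.0548 and 0.024. These gave no sign of pairing, but with 3 arrays for each segment they cannot exclude that the numbers pair the samples. With the replicate block 0 genes and 7 lists passed, the 5 called lists, second heart field and hepatocyte markers (adjusted p = 0.0363 for each of the last pair, and adjusted p = 0.709 with an estimated correlation). With an estimated correlation 0 lists passed in this fit and in every fit without 1 array or without the pair, while fry called 7 without ascending replicate 3, 5 without the pair and 0 in the other fits.

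The mean correlation within segments exceeded that between segments by 0.00253. This was 0.0118 over genes above the 50th percentile, where fewer genes are compared, and 0.000185 to 0.00755 when 1 array was left out. Of 1587 comparisons for 108 genes chosen by the rule or named after their values were seen, 1451 stayed on the same side of the threshold with the same direction, 134 gained a call and 2 changed direction: Adgre1, at -0.64 to 0.0426 when 1 array was left out, and Foxf1, at -0.14 to 0.98. The fit of all arrays called 0 genes, so a gene that stayed on the same side was uncalled in both fits. Those 1451 comparisons therefore support no single gene. Some genes were included because they passed without ascending replicate 3, so their gained calls in that fit were fixed in advance. Of 182 comparisons for 14 lists, 155 stayed the same, 11 gained a call, 10 lost it and 6 changed the direction of the camera test. These were smooth muscle contractile genes, with a median of -0.026 after repeated quantile normalization and -0.041 to 0.0885 when 1 array was left out, macrophage markers, at -0.54 to 0.0816 and at -0.60 without ascending replicate 3 and descending replicate 1, and elastic fibre genes, at -0.030 to 0.0305 and at 0.0429 without ascending replicate 3 and descending replicate 1. None of the reversed values passed the test, and the cause was not tested. Signal over background was not part of the values, so which genes lie near background is not known here.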

Other observations

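Genes of other groups also differed without ascending replicate 3, described here as values chosen after they were seen. Meox2, a homeobox gene of the paraxial mesoderm, fell by 2.34 (adjusted p = 0.00104 by limma), and Ntn1, which encodes the guidance cue netrin 1, fell by 1.61 (adjusted p = 0.000298 by limma). Among vasoactive receptors Agtr2, the vasopressin receptor gene Avpr1a and the endothelin receptor gene Ednrb fell by 2.38, 1.15 and 0.99, while the prostaglandin receptor gene Ptger3 rose by 0.83. The other 12 of 16 measured members of that list did not pass, nor did the list (adjusted p = 0.229 by camera). Dkk2, a Wnt antagonist gene, fell by 1.39 and the Wnt receptor gene Fzd1 rose by 0.81. Of 23 genes of the Wnt list 18 did not pass, nor did the list (adjusted p = 0.926 by camera). Over all 6 arrays none of these genes passed, and ascending replicate 3 gave 8.25 for Meox2 and 9.04 for Ntn1 against descending means of 8.67 and 9.06.

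Ascending replicates 1 and 2 also differed from each other. Tfap2b, a transcription factor gene of the neural crest, stood at 8.73 on replicate 1 and 7.08 on replicate 2, against 6.50 on replicate 3 and 6.59 ± 0.094 (SD, n = 3) in descending aorta. The mesenchymal factor gene Foxf1 stood at 10.8 on replicate 1 and 8.52 on replicate 2, against 9.12 ± 0.27 (SD, n = 3) in descending aorta. The thymus markers Foxn1 and Ccl25 stood at 7.02 and 8.08 on replicate 1 and at 6.17 and 6.93 on replicate 2, and the thymus list did not pass (adjusted p = 0.268 by camera). It passed without ascending replicate 2 (adjusted p = 0.0285 by camera, adjusted p = 0.732 with an estimated correlation). The hepatocyte marker Alb ranged from 7.44 on ascending replicate 1 to 10.1 on descending replicate 2, and that list did not pass either (adjusted p = 0.268 by camera). It passed without ascending replicate 1 and without descending replicate 2 (adjusted p = 0.000499 and 0.00698 by camera), calls lost under the estimated correlation (adjusted p = 0.808 and adjusted p = 0.781 with an estimated correlation).

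The tests on the position of ascending replicate 3, on heart muscle, on the splits of the 5 arrays and on any split with an estimated correlation were chosen after the result was seen, and those on mesothelial cells and on the splits of all 6 arrays before. On 200 genes chosen without it, ascending replicate 3 had a median position of 0.0535 (range 0.00227 to 0.0631 over 3 choices of genes) on the scale from 0 at descending to 1 at ascending aorta. Held-out descending arrays lay at -0.0567, 0.0431 and 0.0836 on the same choices. Held-out ascending replicates 1 and 2 lay at 0.662 and 1.11 on other choices of 200 genes, with 1 set by the other array of the pair. On those choices ascending replicate 3 lay at 0.0133 and 0.0393. On the first 3 choices of genes its median position was 0.0438 on ranks within each array. Because the distributions were made alike before deposit, ranks could hardly give another position, so the normalization was not tested and stays open. The position was 0.0549 on the linear scale, which argues against ascending RNA with a minor share of descending RNA. A candidate explanation that remains is that the array holds descending aorta RNA, through a wrong label or a dissection below the arch, and no descending array lay with the ascending ones as a swap within the series would need. A small share of ascending RNA stays open too: the array lay on the ascending side of both kept descending arrays for 38.5%, 43.5% and 51.5% of the 200 genes, where the held-out descending array did for 29.5%, 42.5% and 54.5%. It lay there beyond all 3 descending arrays for Upk1b, Gata4, Tcf21, Lyve1 and Actc1, genes picked after their values were seen. Over all genes it did so for 2955 of the 6877 at which ascending replicates 1 and 2 lay beyond all 3 descending arrays. What count a further descending array would give was not computed. For Foxd1 the array lay beyond all 3 on the other side. The cardiac list that holds Actc1 had a median of -0.184 on this array. A true difference between embryos in the ascending segment was not tested and stays open.

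The cardiac muscle list was higher in ascending aorta, and heart muscle left on the dissected vessel is a possible explanation. The 15 markers other than Tnnt2 and Tnni1 had a median difference of 0.193 (quartiles 0.0951 and 0.372), below 0.721, which is 50% of the mean difference of Tnnt2 and Tnni1. Without ascending replicate 3 the median was 0.254, with an upper quartile of 0.463, against 1.05. Because those genes are the largest differences of the same list, picked after the values were seen, this comparison excludes nothing, and heart muscle on the vessel stays open, as does expression by cells of the outflow wall, which was not tested.

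More mesothelial or epicardial cells on the dissected ascending aorta may account for the higher mesothelial list. Of 7 mesothelial markers outside that list, the median difference was 0.582, at percentile 100 of 10000 random lists matched on mean expression. Those lists leave out the correlation between markers of a cell type, estimated at 0.554 for the fixed list, whose own call was lost with it (adjusted p = 0.757 with an estimated correlation). Krt7 differed by 1.04, Gpm6a by 0.77, Lrrn4 by 0.76 and Cldn15 by 0.09, and 0 of the 7 passed over all 6 arrays against 4 without ascending replicate 3. Of the fixed list, Upk3b stood at 12.3 and 12.4 on ascending replicates 1 and 2 and at 10.5 on replicate 3. Higher expression per cell was not tested and stays open.

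The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. All 10 gave 0 genes, the real split included. For lists the real split gave 5 and the highest other split 14, and 5 of the 10 splits gave at least as many as the real one. The splits that joined ascending replicates 1 and 2 with a descending array gave 14, 9 and 10 lists. All these list counts come from the preset correlation, and with an estimated correlation each of the 10 splits gave 0 lists. The estimated setting leaves few degrees of freedom, so a count of 0 lists there says little. The 5 arrays without ascending replicate 3 make 10 splits into 2 and 3, again too few for a share under 0.05. There the real split gave 933 genes and the highest other 1, so that 1 split of the 10 reached the real count. For lists it gave 10 and the highest other 11, with 2 of the 10 splits at or above the real count, and with an estimated correlation each split again gave 0 lists.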
